A study of Mus musculus with 6 samples.

How the data were processed

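RNA bound to YTHDF2 was compared with total RNA of the same kind of lysate by RNA immunoprecipitation sequencing (RIP-seq). YTHDF2 is a cytoplasmic protein that binds N6-methyladenosine (m6A) in mRNA and promotes decay of the bound transcripts. Per the labels' protocols, B16F10 cells, a mouse melanoma line, were grown as subcutaneous tumours in mice, and live CD45+CD4+GFP+ regulatory T (Treg) cells were sorted from the tumours of wild-type animals carrying a Foxp3-GFP reporter. The sorted cells were lysed, 10% of the lysate was kept as the Input, and the rest was incubated for 4 hours with beads carrying an anti-YTHDF2 antibody and washed 6 times. Libraries of both kinds were made with a stranded total RNA kit. The series has 6 libraries, 3 of the YTHDF2 immunoprecipitation (IP) and 3 of the Input, numbered as replicates 1 to 3 in each group. The labels do not say whether the replicates came from separate animals or pools, so p-values measure only the spread between these libraries, which may be technical. A control precipitation without the specific antibody, or from cells lacking YTHDF2, was not analysed here, so enrichment below means abundance in the IP relative to the Input.

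The values in each deposited file are raw counts of reads per Ensembl gene identifier (ID), 1 file per library. Per the submitters' processing notes, the authors used Trimmomatic 0.39, HISAT2 2.1.0, HTSeq and DESeq2 with the mouse build mm10. The notes give no role or order, and the HTSeq version, annotation release, strand setting and handling of duplicate reads are not given in the sources used here. The kit marks strand, and whether the counts were made on the intended strand was not tested here, so each count and enrichment rests on the assumption that they were. Each file lists 54446 gene IDs, 92 spike-in IDs and the 5 summary categories that HTSeq writes. The spike-in IDs held 0 to 2 reads per library and were left out. The summary categories also stayed out of library sizes and tests. Reads in no annotated feature made up 49.6% to 51.6% of the reads in an Input file and 71.2% to 72.1% in an IP file. Gene-assigned reads numbered 10029733 to 14704617 per Input library and 6847731 to 8465453 per IP library. The libraries carry no molecular identifiers in these files, so the Poisson interval and the detection floors cover counting error only.

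The files do not pair gene IDs with symbols, and 0 of the 49997 rows of the reference gene table used here held an Ensembl ID, so no ID was given a name, class, position or length. For this reason the gene lists and marker lists fixed before the data were examined, among them the negative regulators of NF-kB signalling, the Treg markers and the markers of other cell types, were not tested. Shares of reads by RNA class and relations to transcript features were not computed either.

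Gene counts were tested with the quasi-likelihood F-test of edgeR 4.0.16 in R 4.3.3 (filterByExpr, TMM factors, robust dispersion, group as the only term, two-sided). Genes with a Benjamini-Hochberg adjusted p under 0.05 were called enriched when the log2 fold change of IP over Input was above 0 and depleted when it was below 0. Enrichment of at least 2-fold required a log2 fold change of at least 1. CPM values were computed here from the counts with TMM-scaled library sizes, and standard errors of log2 fold changes from the F statistics. Apart from the most abundant ID of each group, the IDs printed were chosen by a rule fixed before the data were examined. It took the largest log2 fold changes in each direction among called genes with a mean of at least 10 CPM. All IP libraries also had to lie on 1 side of all Input libraries. The rule takes 10 IDs per direction, and the first 2 in each are printed because unnamed IDs carry no annotation. Its condition on symbols and its parts on Ythdf2 and on the gene lists were not applied. Where a group had 0 reads, a fold is given against a floor of 3 reads per library, which is a bound for counting error only. Library measures were compared by exact two-sided permutation tests, whose smallest p for 3 against 3 libraries is 0.1.

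The test was checked on simulated counts for 15615 genes with the depth of each library. Apart from the changes set, each gene had a mean pooled over all libraries and a dispersion shared by IP and Input. The real IP libraries varied more than the Input libraries, so the recovery given here may not hold for these data. It recovered 3 of 100 genes changed 2-fold and 22 of 100 changed 4-fold, with the right sign in each. Among the genes at or above the upper quartile of level, these shares were 11.1% and 81.5%. Of the 29 calls, 4 were genes that had not been changed. The real data gave 1630 calls, so the Benjamini-Hochberg adjustment was stricter in the simulation. The shares recovered are therefore not the power of the test on the real data.

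Alternatives fixed before the data were examined were other size factors, other count filters, DESeq2 1.42.0, limma 3.58.1 (voom with quality weights), a replicate block, thinning to the smallest library, leaving out each library, and a test against a 1.5-fold change. Library sizes from all reads and removal of the 10 most abundant gene IDs were added after the data were seen. Sets of cell cycle genes came from the classifier of scran 1.30.0 by Ensembl ID and were tested with camera and fry of limma.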

Results

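Transcripts recovered with YTHDF2 in Treg cells from B16F10 tumours were measured in 3 IP libraries and compared with 3 Input libraries. The IP libraries held 27021435 to 34052273 reads in all categories and the Input libraries 26665143 to 36717111. Of these, 24.8% ± 0.576 (SD, n = 3) were assigned to a gene in the IP and 38.9% ± 1.22 (SD, n = 3) in the Input. A read was found for 14200 to 19991 gene IDs per IP library and for 26250 to 33344 per Input library. No pair of replicates was a repeat of one library: the chi-square statistic per degree of freedom between 2 libraries of a group was at least 16.1, where sampling noise alone gives about 1.

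The composition of the IP libraries differed from that of the Input. The gene ID with the most reads in the IP, ENSMUSG00000097971.3, took 8.05% ± 0.879 (SD, n = 3) of gene-assigned reads there and 1.73% ± 0.358 (SD, n = 3) in the Input. The gene ID with the most reads in the Input, ENSMUSG00000064339.1, took 5.84% ± 0.500 (SD, n = 3) there and 0.0850% ± 0.0509 (SD, n = 3) in the IP. These genes changed by a log2 fold change of 2.09 ± 0.16 (SE) and of -6.21 ± 0.43 (SE), with adjusted p-values of 5.81e-05 and 3.50e-05 in edgeR's quasi-likelihood test. Both were chosen for their level after the values were seen. Reads in no annotated feature made up 71.7% ± 0.434 (SD, n = 3) of the IP files and 50.4% ± 1.08 (SD, n = 3) of the Input files. Reads without a unique alignment made up 3.09% ± 0.242 (SD, n = 3) and 9.44% ± 0.244 (SD, n = 3). For both of these read categories, the 3 IP libraries lay on 1 side of the 3 Input libraries. The exact two-sided permutation test gave p = 0.1 for each category, the smallest this design allows. The adjusted value over the 11 library measures tested was also 0.1.

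**Figure D1:**
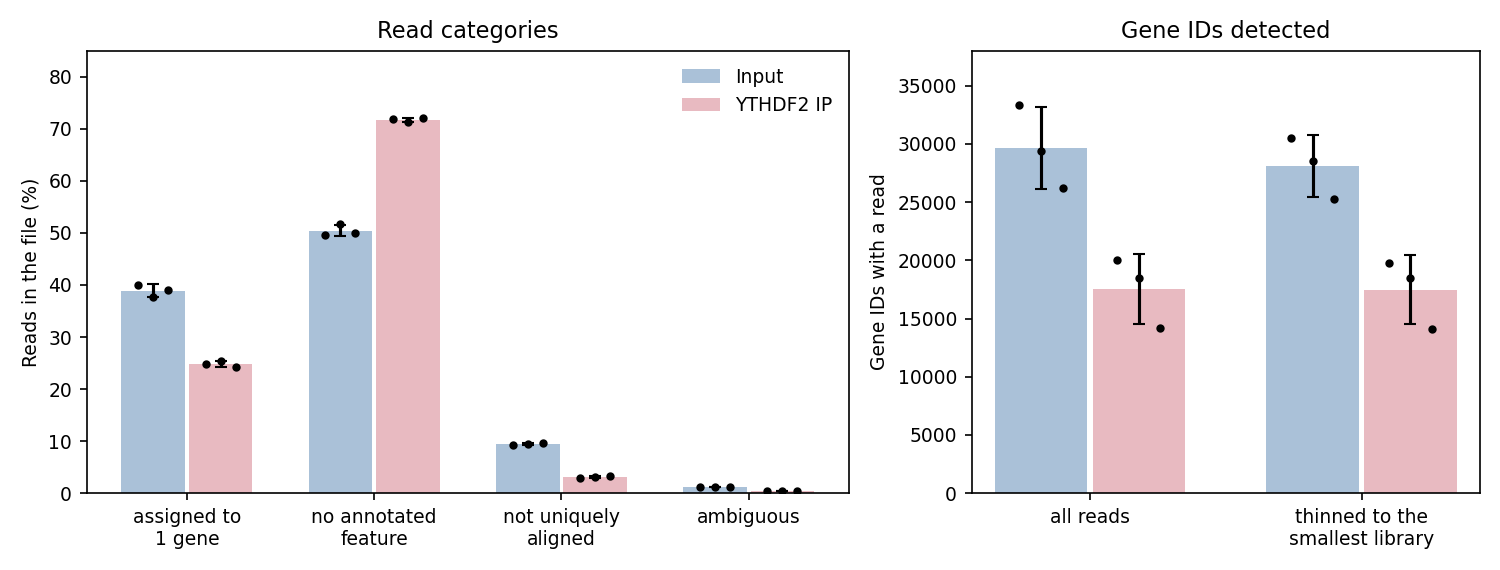
Left, percent of the reads of a file in each category; right, number of gene IDs with a read , with all gene-assigned reads and after thinning every library to 6847731 reads. Bars are means of 3 libraries, error bars the SD and points the libraries; the IP libraries list fewer gene IDs than the Input libraries in both settings.

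The series asks which transcripts YTHDF2 binds in these cells. Of 15615 genes tested, 676 were enriched in the IP and 954 were depleted, and 13985 did not pass the test. An estimated enrichment of at least 2-fold was found for 404 genes and depletion of at least 2-fold for 858. In a test against a 1.5-fold change (glmTreat of edgeR), 205 genes were enriched and 591 depleted. The enriched genes had a median log2 fold change of 1.08 (quartiles 0.87 and 1.49). They took 14.4% ± 1.24 (SD, n = 3) of gene-assigned reads in the Input and 35.4% ± 0.669 (SD, n = 3) in the IP. The depleted genes had a median log2 fold change of -2.08 (quartiles -3.18 and -1.42), and their share fell from 34.2% ± 0.712 (SD, n = 3) in the Input to 7.67% ± 0.290 (SD, n = 3) in the IP. These shares describe genes selected on the same libraries.

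All 676 enriched genes lay higher in every IP library than in every Input library, and all 954 depleted genes lay lower. The calls were made on these same libraries, so this separation adds no support to them. Over all tested genes, the groups did not overlap for 36.5%, where chance gives 10% for a single gene. The IP lay above the Input for 1994 of these genes and below it for 3700. Genes of the same libraries are not independent, so the share of 36.5% carries no test. Every enriched gene had reads in all IP libraries and in the Input. Among the depleted genes, 35 had no read in any IP library. Against a floor of 3 reads per library, these were at least 14.1-fold to at least 57.4-fold lower in the IP. At that floor all 35 still lie below the median of the depleted genes, which is therefore -2.08 by construction either way. The floor covers counting error only and does not limit the true level: of genes expected at 20 to 50 reads, 31.7% to 59.6% had no read in an IP library. Of the tested genes, 234 had reads in all 3 Input libraries and none in the IP, and 2 had reads in all 3 IP libraries and none in the Input.

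The gene ID with the largest enrichment under the rule, ENSMUSG00000076890.1, had 32.3 ± 16.8 CPM (SD, n = 3) in the IP and 1.27 ± 0.811 CPM (SD, n = 3) in the Input. Its log2 fold change was 4.66 ± 0.85 (SE), with an adjusted p of 0.00801 in edgeR's quasi-likelihood test, and the call held in the 17 alternatives that gave it a value. The next, ENSMUSG00000081264.1, had 24.0 ± 17.7 CPM (SD, n = 3) and 1.83 ± 1.15 CPM (SD, n = 3), a log2 fold change of 3.70 ± 0.95 (SE) and an adjusted p of 0.0371 in the same test. Over the alternatives its log2 fold change ranged from 2.91, without IP replicate 3, to 4.12, without Input replicate 1. This second call was lost in 7 of 17 alternatives, over which the adjusted p ranged from 8.57e-05 to 0.160. It was lost with each of 5 libraries left out in turn, with adjusted p-values from 0.0601 upwards. It was also lost with a replicate block, with an adjusted p of 0.0808, and with library sizes from all reads, with an adjusted p of 0.0620.

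The first depleted gene ID under the rule, which ranks fitted values, was ENSMUSG00000025289.15, with 21.9 ± 3.52 CPM (SD, n = 3) in the Input and no read in any IP library. Against the floor of 3 reads it was at least 57.4-fold lower in the IP, for counting error only and with the drop-out of single IP libraries left out, with an adjusted p of 0.00296 in edgeR's quasi-likelihood test. The next, ENSMUSG00000099250.1, had 36.0 ± 20.8 CPM (SD, n = 3) in the Input and 1 read over the 3 IP libraries. The pooled ratio of Input to IP was 799, with a 95% Poisson interval for counting error of 143 to 31586. The IP read lay in IP replicate 2. Without that library no IP read is left, and the fitted log2 fold change was -11.6 in place of -9.34. As the first had no read in the IP, the data do not show which of these genes was depleted more. The adjusted p of ENSMUSG00000099250.1 was 0.000973 in edgeR's test and 0.0593 in limma voom, the 1 of 17 alternatives in which the call was lost, and the lowest was 2.71e-14.

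**Figure D2:**
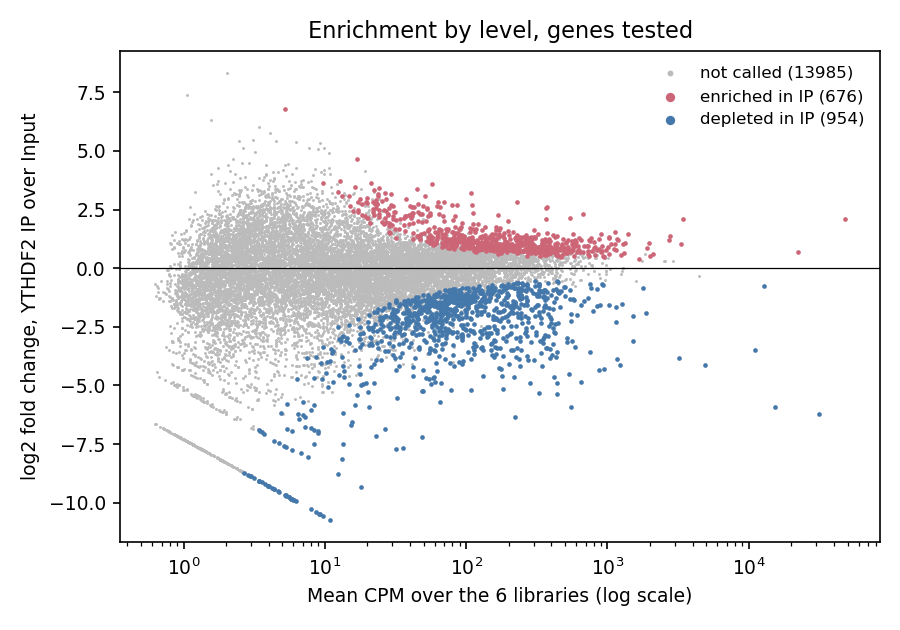
Log2 fold change of YTHDF2 IP over Input against the mean CPM over the 6 libraries (log axis) for the 15615 genes tested; each point is a gene, coloured by call at an adjusted p under 0.05 in edgeR's test. Called genes lie mostly at high levels, and the slanted rows at the lower left are genes without a read in the IP, whose fitted values depend on the prior count.

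Calls were concentrated among abundant transcripts. In the group above the upper quartile of mean level, from 49.9 CPM upwards, 572 of 3904 genes were enriched and 659 were depleted. In the group below the lower quartile, up to 3.55 CPM, 0 were enriched and 10 depleted. The spread between replicates followed the same order: the median coefficient of variation was 24.2% in the IP and 11.6% in the Input in the group of highest level, and 129% and 61.2% in that of lowest level. Enrichment computed within each replicate number, from libraries that share no control, agreed more closely for abundant genes. Pearson's r across genes between replicates was 0.31 to 0.38 over all tested genes and 0.88 to 0.93 over the 2151 genes with a mean of at least 100 CPM. Genes are not independent replicates, so these correlations carry no test. A missing call in the group of lowest level does not show that a gene was not enriched.

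The balance of enriched and depleted genes depended on the scaling. Enriched genes were 41.5% of the calls with TMM factors, 57.4% with upper quartile factors and 51.8% with total counts. When library sizes included the reads outside genes, they were 7.55% of the calls, with 160 genes enriched and 1958 depleted, and the median log2 fold change of all tested genes was -0.65 in place of -0.12. The direction of a single gene close to the median is therefore relative to the scaling. This reached called genes as well: with library sizes from all reads, 4 of the genes called with TMM factors changed sign.

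Leaving out single libraries moved the counts as well. These fits had 2 libraries in the reduced group and tested 17025 to 19027 genes against 15615. Lower power and other genes are thus mixed with any influence of the library itself. Leaving out IP replicate 1 or 2 gave 362 or 389 enriched genes, and leaving out Input replicate 1, 2 or 3 gave 361, 239 or 188. Without IP replicate 3, which listed the fewest gene IDs, 999 genes were enriched and 1661 depleted, and 628 of the enriched and 953 of the depleted genes were shared with the full set. Without Input replicate 2 or 3, 606 or 563 genes were depleted. DESeq2's Wald test called 1382 genes enriched and 2085 depleted, and these included 676 of the 676 enriched and 941 of the 954 depleted genes of edgeR.

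**Figure D3:**
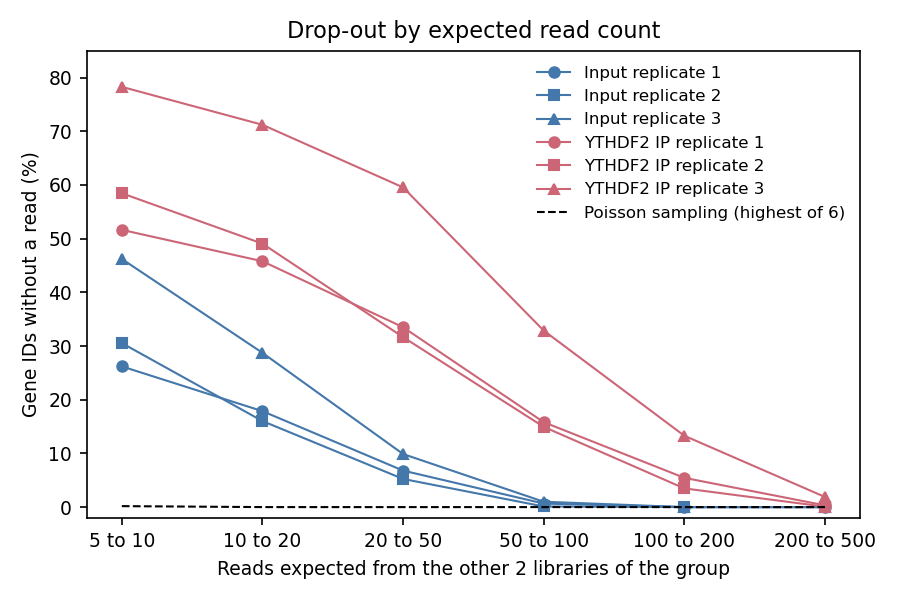
Percent of gene IDs without a read in a library (vertical axis) among those for which the other 2 libraries of its group predict the number of reads on the horizontal axis, for each of the 6 libraries. At 50 to 100 expected reads the 3 IP libraries lie between 15.0% and 32.9% and the 3 Input libraries between 0.114% and 0.998%; the dashed line is the share that Poisson sampling alone would give.

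Some genes that the other 2 IP libraries placed at intermediate level had no read in an IP library. The prediction sums the other 2 libraries, so a gene with reads in only 1 of them also counts. Among genes for which the other 2 IP libraries predict 50 to 100 reads, 15.8% (95% Clopper-Pearson interval 14.4% to 17.4%) had no read in IP replicate 1. The share was 15.0% (13.5% to 16.5%) in IP replicate 2 and 32.9% (30.9% to 35.0%) in IP replicate 3. In the Input libraries it was at most 0.998% (0.593% to 1.57%). These intervals treat the genes of 1 library as independent draws and do not cover the spread between libraries. The exact two-sided permutation test of the group means gave p = 0.1, the smallest possible. Each share was computed within the real groups and would change under another split. The measure was also chosen after its result was seen, so this p adds no support.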

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

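The test of read drop-out was chosen after its result was seen; the thinning and overlap tests were chosen after the number of gene IDs per library was seen, but before their own results were. One result was flagged because it lies outside the gene counts: reads in no annotated feature made up 71.7% of an IP file on average against 50.4% of an Input file, and the lowest IP library, at 71.2%, lay above the highest Input library, at 51.6%. No explanation of it was tested.

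IP libraries listed fewer gene IDs than Input libraries. Lower depth of gene-assigned reads does not account for this: after thinning every library to 6847731 reads, the Input library with the fewest still listed 25232 gene IDs and the IP library with the most listed 19768. That fewer distinct RNA molecules were amplified in the IP stays open: the idea was formed from the drop-out values (at 50 to 100 expected reads, 15.0% of genes without a read in the lowest IP library and 0.998% in the highest Input library), which cannot test it. Recovery of one reproducible subset of transcripts stays open as well: 1464 genes at 1 CPM or more in the Input had no read in all 3 IP libraries, 1.40 times the 1049 expected if the libraries missed genes independently within bins of Input level. That ratio lies above chance and below the 1.5 that was set in advance for this explanation.

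The 3 counts of calls were set against the 10 splits of the 6 libraries into 3 and 3, the real one included. In edgeR's test the real split gave 676 enriched genes, 954 depleted genes and 404 genes enriched at least 2-fold, and the highest of the other splits gave 0 for each. For each count, 1 of the 10 splits was as large, the real one, and 10 splits are too few for a share under 0.05. The other splits mix IP and Input libraries on each side, so the difference between the groups enters their spread. Their counts of 0 therefore add no support.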

How the results depend on the processing

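No gene ID printed under the rule reversed its direction in the 17 alternatives that gave it a value. These leave out the filter of 1 CPM in all libraries and the test against a 1.5-fold change. Of all genes called in the main setting, 4 reversed with library sizes from all reads. The number of enriched genes was 1081 with upper quartile factors, 1030 with a filter of 1 CPM in all libraries, 1382 with DESeq2, 1152 with limma voom and 160 with library sizes from all reads, against 676. Enrichment of at least 2-fold was found for 733, 607, 970, 652 and 92 genes in the same order, against 404. The number of depleted genes was 2085 with DESeq2 and 1958 with library sizes from all reads, against 954. Enriched and depleted genes together numbered 3467 with DESeq2 and 796 (205 enriched and 591 depleted) in the test against a 1.5-fold change, against 1630. The cause of these shifts was not tested, except that a test against 1.5-fold asks for a larger change. Leaving out 1 library gave 188 to 999 enriched genes, 563 to 1661 depleted genes, 140 to 588 genes enriched at least 2-fold and 751 to 2660 calls in all. Against the main setting, the median log2 fold change of the genes also tested there moved by 0.20 with upper quartile factors, by 0.12 with total counts, by -0.53 with library sizes from all reads, by -0.29 with limma voom and by -0.38 with a replicate block. It also moved by 0.18 with the filter of 1 CPM in all libraries, by 0.10 with that of a mean count of 50, and by -0.15 and -0.11 without IP replicate 1 and 2. The filters tested 8961 and 10650 genes against 15615, so their medians cover fewer genes and are not shifts of scaling alone. A replicate block gave 833 enriched and 1095 depleted genes. The labels do not say whether libraries of equal number share a lysate, and the numbers were not taken to pair the libraries. Deviations from the group means of same-numbered libraries correlated at 0.0999, 0.026 and 0.024, and each library correlated best with its own number in the other group. These correlations cover tested genes of every level, noisy ones included, so they cannot exclude pairing. DESeq2 gave no adjusted p for 19225 of 40072 genes with a read. Settings that need gene names or lengths were not run: TMM over nuclear genes only, both corrections for GC content and length, and all alternatives for gene lists, RNA classes and transcript features.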

Other observations

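The cell cycle test below was chosen after the gene counts were seen, and its prediction was written before its own result was. Cell cycle genes were the 1 group of genes examined by ID. In the classifier of scran, genes that only rank as the higher member of a pair for a phase form a set; 82 G1, 156 S and 103 G2M genes were tested. Of the G1 genes, 3 were enriched and 6 depleted in the IP. Of the S genes, 6 were enriched and 12 depleted, and of the G2M genes 2 and 6. The shares enriched were 3.66%, 3.85% and 1.94% and those depleted 7.32%, 7.69% and 5.83%, in the order G1, S and G2M. Over all tested genes they were 4.33% and 6.11%. The median log2 fold change was -0.33 for G1, -0.30 for S and -0.34 for G2M genes, against -0.12 for all tested genes. The sets had median levels of 39.3, 32.5 and 24.9 CPM. Genes between the median and the upper quartile of level, 13.5 to 49.9 CPM, had a median log2 fold change of -0.22. Of these, 2.54% were enriched and 5.30% depleted. The median and shares over all tested genes are thus not a comparison at equal level.

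The hypothesis that these genes are recovered at a different level from other genes was not settled: camera with an estimated correlation gave adjusted p-values over the 3 phases of 0.523 for G1, 0.859 for S and 0.523 for G2M. With the preset correlation they were 0.683, 0.819 and 0.683. For the S genes, camera's direction was up while their median was below 0. A p that misses the threshold does not show equal recovery, so the bound written for this test before its result was seen, a p of 0.05 or more, was too weak to exclude the hypothesis. By fry, which does not compare a set with other genes, the sets moved down on balance with unadjusted p-values of 0.00128 for G1, 0.0349 for S and 0.00330 for G2M under TMM scaling. This depends on the scaling for the S genes, whose p was 0.327 with upper quartile factors and 0.0533 with total counts. Over TMM, RLE, upper quartile, total count and all-read scaling, run after the data were seen, the direction was down for each set, with p-values of at most 0.00305 for G1 and 0.0157 for G2M.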
